A study of Mus musculus with 3 samples.

How the data were processed

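Gene expression was measured with 1-colour microarrays in mouse embryonic fibroblasts (MEFs) on day 5 after viral infection. Per the labels, total RNA was extracted with TRIZOL, purified on columns with DNase, amplified, labelled with Cy3 and hybridised to 1 array per sample. The 3 samples were SKO+Flag, SKOM+Flag and SKOM+Srebp1, with 1 array per group. Groups were taken from the sample titles. Per the file headers, the SKO+Flag and SKOM+Flag arrays were on slide 1 and the SKOM+Srebp1 array was alone on slide 2. Slide and group therefore cannot be told apart in any comparison with the SKOM+Srebp1 array.

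The scanner files hold spot intensities on a linear scale, which per the file headers were made with Agilent Feature Extraction 10.7.3.1 (10.7 per the submitters' processing notes). The processed signal is background-corrected and detrended by that software and comes with an error estimate for each spot, per the file headers. The authors also deposited log2 values normalised between arrays, in 2 tables that were identical probe by probe and held 24455 non-control probes. The method behind the authors' log2 values is not given in the sources used here. Their 3 column medians were 8.44, 8.44 and 8.45, and their ratios between arrays correlated across probes at 0.9999 or more with ratios from quantile-normalised processed signals (smallest r = 0.999915). The scale and direction of the authors' values were settled by that comparison, whereas their centring stays unknown.

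Each array held 45018 spots, of which 43379 were not controls and represented 41174 probes. Spots that the scanner software had marked as outliers were left out (74 on SKO+Flag, 93 on SKOM+Flag and 71 on SKOM+Srebp1). No spot was saturated (0 on each array). The main values were log2 of the processed signal minus the array's own 75th percentile over non-control probes, which was 541, 602 and 516 intensity units on SKO+Flag, SKOM+Flag and SKOM+Srebp1. Spots of a probe were averaged, and for a gene with several probes the probe with the highest mean over the 3 arrays stood for the gene. A gene counted as measured in a comparison when it was well above background, by the scanner software's own mark, on at least 1 of the arrays compared. A gene well above background on 1 array only has a bound. The brighter array's value was set against the higher of the dim probe's own value and the lowest signal well above background on the dim array, and the result is written "at least N-fold". Where the dim probe's own value was the higher, the bound equals the plain ratio. No scanner error is taken off a bound.

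Probes were named through the accession given for them in the scanner files, matched without version to a RefSeq gene table of assembly GRCm38.p6 (27479 probes). Where that failed, the symbol in the authors' annotated table was used, either current (2404 probes), updated through a synonym (305) or kept as given (372). In this way 30560 probes stood for 19578 genes and 10614 probes stayed unnamed. Where both names existed, they differed for 1964 of 19472 probes, and the accession's name was used. The array headers name the build mm9, which differs from that of the gene table, so no coordinates are given. There were 7712 genes with more than 1 probe.

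With 1 array per group no test between groups was possible, and no p-values were computed. Genes were counted by a rule of size, 2-fold or more, with one-sided genes counted by their bound. The scanner software's error estimates for the spots were combined into an error for each log2 ratio. This error is technical and holds neither biological spread nor spread between arrays. The median error was 0.20 log2 units in each comparison. It was nearly the same, about 0.204, for many bright genes, so it is not a spread measured gene by gene. Errors of several spots of a probe were combined as if independent. Smaller errors such as 0.06 therefore do not show that a gene was measured better. A second technical measure came from probes printed 10 times on an array, whose spots had a median SD of 0.0650, 0.0650 and 0.0622 log2 units (170, 170 and 169 such probes). For arrays, their number limits the precision.

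Before the data were examined, 27 gene lists with 616 symbols were fixed. They covered cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, ribosome biogenesis and Myc-linked growth, ribosomal proteins, pluripotency, epithelial genes, fibroblast and mesenchymal genes, TGF-beta response and contractile genes, cell cycle and mitosis, DNA replication, p53 targets with cell cycle inhibitors and senescence, glycolysis, oxidative phosphorylation, interferon response, inflammatory cytokines and NF-kB, unfolded protein and integrated stress response, LXR targets and sterol efflux, fatty acid oxidation and PPAR targets, reprogramming barriers and early regulators, a housekeeping reference, and markers of adipocytes, macrophages and immune cells, endothelium, neural cells, skeletal muscle, keratinocytes and stratified epithelium, and extraembryonic endoderm and trophoblast. No named probe was matched here for 9 symbols (Nanog, Fgf4, Prdm14, L1td1, Trim71, Spint2, Mx1, Lif and Dsc3), which were not analysed here. A list's median log2 ratio was ranked among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list is called high at percentile 97.5 or more and low at 2.5 or less. Genes in a list are not independent, so the percentile is a description of these libraries.

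The rule for the genes named in the text was also set before the data were examined. It takes, per comparison, the factor genes, and the 8 highest and 8 lowest ratios among genes well above background and not saturated on both arrays that reached 2-fold with the 75th percentile, with quantile normalisation and with the authors' values alike. It adds the 4 largest bounds in each direction, and for each list up to 4 members with the largest change, along with members that show a mixed direction. The rule passes over predicted and clone-based genes in its first 2 parts and leaves out genes tied to sex. Genes named beyond this rule, such as Fasn, were chosen after their values were seen. Results for some genes that the rule takes are not reported here.

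Each alternative changed one choice, with 2 exceptions. The authors' values also brought their own set of probes and left 14058 genes in each comparison, and normexp correction also put raw spot signals in place of the scanner software's corrected and detrended ones. The alternatives were quantile normalisation, the 75th percentile over probes well above background on all 3 arrays, normexp background correction with an offset of 50, the authors' values, a filter for genes well above background on both arrays, no filter, the mean of a gene's measured probes, and a 1.5-fold rule. Normexp was to start from mean spot signals. The scanner files used here give median spot signals, so the median signal and the median local background took that place. Scaling to the 8 spike-in transcripts was added after seeing the data. It shifted the median of all genes by 0.34 in SKOM+Flag against SKO+Flag, by -0.37 in SKOM+Srebp1 against SKOM+Flag and by -0.03 in SKOM+Srebp1 against SKO+Flag. Scaling by the median difference of the 8 spike-ins between arrays, also added after seeing the data, gave shifts of 0.30, -0.27 and 0.014 in the same order. Normexp correction shifted it by 0.14 in SKOM+Flag against SKO+Flag, and no other shift passed 0.1.

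The procedure was tested on simulated data made from the levels of 13849 genes with the scanner error as the only noise. Simulated changes of 3-fold and 4-fold were called in the right direction in 100% of genes in each of the 3 comparisons, and changes of 2-fold in 50%, 46% and 46%. Of 13649 unchanged genes, 0.0220%, 0.0293% and 0.0220% were called. Of 100 random lists without an effect, 5, 4 and 5 were called high or low. These shares follow largely from the cut-offs and the assumed noise. Random lists hold unrelated genes, so they do not test lists of genes that vary together. Every simulated gene counted as well above background on both arrays, so the rule for bounds was not tested. Comparisons that share an array were set against 100 simulations in which no gene changed.

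Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (lowess) and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 (normexp).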

Results

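Messenger RNA levels were compared between 3 cultures of mouse embryonic fibroblasts (MEFs), primary connective tissue cells that can be reprogrammed towards pluripotent stem cells by adding transcription factors. In the field's shorthand SKO stands for Sox2, Klf4 and Oct4, and SKOM adds c-Myc. The cultures had been infected with SKO plus a construct labelled Flag, with SKOM plus Flag, or with SKOM plus Srebp1, a transcription factor best known for activating genes of lipid synthesis. They were grown for 5 days in serum-containing medium with Lif, a cytokine used for mouse stem cells. The series' title names the question as which genes Srebp1 and c-Myc regulate during reprogramming. Each group had 1 array and no replicates, so the differences below have no replicate check, and the number of arrays limits their precision. Of 41174 probes, 25619 (62.2%) were well above background on the SKO+Flag array, 26094 (63.4%) on the SKOM+Flag array and 26188 (63.6%) on the SKOM+Srebp1 array. Values are log2 ratios of signals scaled to each array's 75th percentile, and ± gives the scanner software's error, which is technical only. Percentiles place a list's median among 10000 random lists of like size and level, as a description of these libraries.

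The factor genes were read first, as a check of the labels, and checked them only in part. Of 3 probes for Myc (c-Myc), 2 were brighter in SKOM+Flag than in SKO+Flag, with log2 ratios of 2.76 ± 0.20 and 3.79 ± 0.21, or 6.76-fold and 13.8-fold. The remaining Myc probe was lower (-2.33 ± 0.06). SKOM+Srebp1 differed little from SKOM+Flag at all 3 Myc probes, with ratios of -0.20, -0.05 and -0.15. The probe for Srebf1, the gene for Srebp1, was 1.58-fold brighter in SKOM+Srebp1 than in SKOM+Flag (0.66 ± 0.20) and nearly equal in the cultures without added Srebp1 (-0.07 ± 0.20). Pou5f1 (Oct4) was bright on all 3 arrays, at 3.06, 2.73 and 2.65 log2 units above the 75th percentile. Klf4 was bright as well, at 4.93 in SKO+Flag, 4.28 in SKOM+Flag and 3.44 in SKOM+Srebp1. Its ratios were -0.65 ± 0.20 in SKOM+Flag against SKO+Flag and -0.84 ± 0.20 in SKOM+Srebp1 against SKOM+Flag. In SKOM+Srebp1 against SKO+Flag its ratio was -1.49 ± 0.20. Whether the cultures received equal amounts of the factors was not tested. The Sox2 probe was not well above background on any array. Where these probes lie in the transcripts is not given in the sources used here, so a probe outside the part carried by a virus would check nothing. Of 4 probes for the related gene Srebf2, 3 had small positive ratios with Srebp1 (0.14, 0.17 and 0.25) and 1 had a ratio of -0.41.

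**Figure D1:**
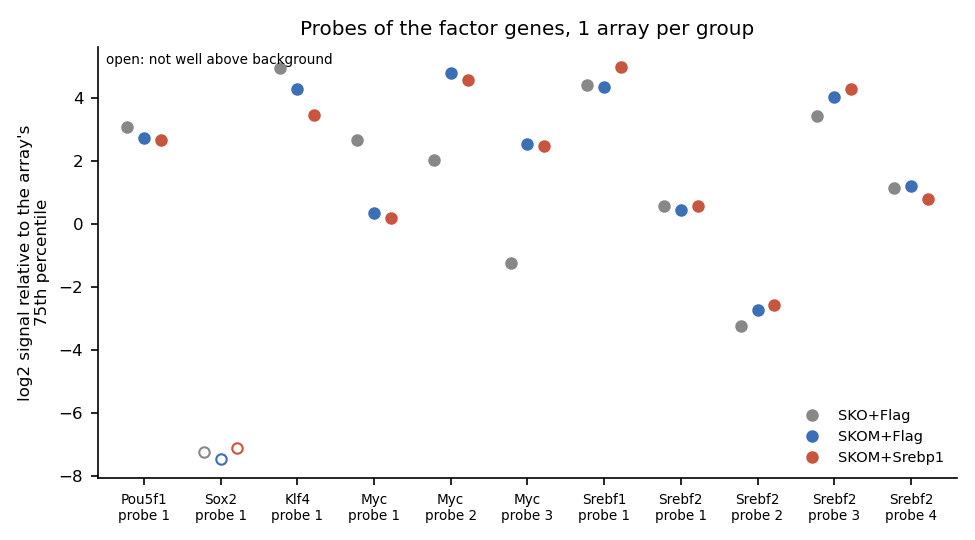
Level of each probe of the factor genes (vertical axis, log2 signal relative to the array's 75th percentile), with 1 point per array in grey for SKO+Flag, blue for SKOM+Flag and red for SKOM+Srebp1, and open points for probes not well above background. Myc probes 2 and 3 were brighter in SKOM+Flag than in SKO+Flag by 2.76 and 3.79 log2 units and Myc probe 1 had a ratio of -2.33, while the Srebf1 probe was brightest in SKOM+Srebp1 at 4.98.

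SKOM+Flag against SKO+Flag shows what accompanied c-Myc. The culture with c-Myc had higher levels of genes for making ribosomes, replicating DNA and dividing, and lower levels of genes typical of fibroblasts, of contractile cells, of the interferon response and of macrophages. Dkc1 and Nolc1, which act in ribosomal RNA maturation, were higher by 2.29 ± 0.20 and 1.83 ± 0.20. Dcn and Lum, proteoglycans of the fibroblast matrix, were lower at -2.46 ± 0.20 and -2.56 ± 0.21. Of 14987 genes measured on at least 1 of the arrays, 1039 were at least 2-fold higher (928 measured on both arrays and 111 by their bound) and 1920 at least 2-fold lower (1644 and 276). Lower calls made up 64.9% of all calls among named genes, but 33.1% when the arrays were scaled to the spike-in transcripts. That scaling shifted the median of all genes by 0.34. The ratios given are therefore relative to the bulk of genes, whose median was -0.05. The SD of ratios over genes was 0.79. Normexp correction, which shrinks ratios of dim genes, took 24 of the genes picked for naming from 2-fold or more to below it and left 83 at 2-fold or more.

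Growth genes stood out. Of 31 measured genes of ribosome biogenesis and Myc-linked growth, 25 were at least 2-fold higher and 30 lay above 0, with a median ratio of 1.30 at percentile 100. They included Shmt1 (3.13 ± 0.22), an enzyme of one-carbon metabolism, Cad (2.15 ± 0.20), which starts pyrimidine synthesis, and Polr1b (1.88 ± 0.20), a subunit of RNA polymerase I. All 26 ribosomal protein genes lay above 0 (median 0.52, percentile 100), 4 of them at 2-fold or more, led by Rpl4 (1.37 ± 0.20) and Rpl3 (1.24 ± 0.20). With quantile normalisation the median of the ribosomal proteins was 0.35. Among 25 DNA replication genes, 11 were at least 2-fold higher, with a median of 0.90 at percentile 100. Examples were the origin licensing factors Cdc6 (1.62 ± 0.21) and Cdt1 (1.56 ± 0.20) and the helicase subunit Mcm7 (1.44 ± 0.20). Cell cycle and mitosis genes were shifted by less but together. Of 28, 27 lay above 0 and only Bub1b (1.22 ± 0.20) reached 2-fold, with a median of 0.53 at percentile 99.99.

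The pluripotency list leaned higher, with 15 of 21 measured members above 0 and a median of 0.43 (0.37 with one-sided genes at their bounds) at percentile 99.38. The call is not settled. The random range ended at 0.254, and the median was 0.253 with the authors' values, 0.252 over genes measured on both arrays and 0.11 without a filter on dim genes, all inside that range, against 0.45 with quantile normalisation and 0.52 after normexp correction. Fbxo15, an early reprogramming marker, was higher by 2.21 ± 0.30, Dnmt3b, a DNA methyltransferase of early embryonic cells, at least 9.94-fold and Nr0b1 at least 6.93-fold. After normexp correction the bound of Dnmt3b was 1.62 log2 units, against 3.31 in the main setting. Lefty1 went the other way (-1.92 ± 0.23), and Gdf3 was at least 1.12-fold higher.

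Fibroblast and contractile genes were lower. Of 32 fibroblast and mesenchymal genes, 14 were at least 2-fold lower, none reached 2-fold higher (0) and 29 lay below 0, with a median of -0.92 at percentile 0. Pdgfra, the PDGF receptor of mesenchymal cells, stood at -2.30 ± 0.08 (-0.61 after normexp correction) and Lox, which crosslinks collagen, at -1.94 ± 0.20. All 20 genes of TGF-beta response and contraction lay below 0, 16 of them at least 2-fold, with a median of -1.46 at percentile 0. Among them were Ltbp2 (-2.01 ± 0.20), Myl9 (-1.80 ± 0.20) and Cnn1 (-1.71 ± 0.20), the last 2 of the contractile apparatus.

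Immune and interferon genes were lower too. Of 27 interferon response genes, 21 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -1.75 at percentile 0. Rtp4 (-2.53 ± 0.21), Oasl2 (-2.50 ± 0.23) and Usp18 (-2.42 ± 0.21) are classical interferon-induced genes. Of 19 inflammatory cytokine and NF-kB genes, 9 were at least 2-fold lower (median -0.89, percentile 0), among them Il11 (-1.58 ± 0.20), Il1rl1 (-1.88 ± 0.21) and Csf1 (-1.52 ± 0.06). Without a filter on dim genes that median was -0.57. Macrophage and immune markers moved with these groups. Of 17, 12 were at least 2-fold lower and 16 below 0, with a median of -1.80 (-1.57 with bounds) at percentile 0, for example Laptm5 (-2.23 ± 0.21), Itgam (-2.13 ± 0.25) and C1qa (-2.11 ± 0.36). Cd74 was the marker above 0, and it was at least 2-fold higher. After normexp correction the medians of the interferon and macrophage lists were -0.58 and -0.49, and Oasl2, Itgam and C1qa stood at -0.998, -0.61 and -0.16, no longer 2-fold lower.

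Cholesterol genes were lower in the culture with c-Myc. Of 24 genes of cholesterol synthesis and uptake, 23 lay below 0 and 6 were at least 2-fold lower (median -0.54, percentile 0.02). Tm7sf2, Msmo1 and Hsd17b7, enzymes of sterol synthesis, stood at -1.38 ± 0.20, -1.25 ± 0.20 and -1.19 ± 0.20. Fatty acid and triglyceride synthesis showed no common direction, with 8 of 20 members above 0, a median of -0.16 at percentile 19.25, and Elovl6 (1.07 ± 0.20) against Acss2 (-0.85 ± 0.20). LXR targets and sterol efflux genes were called low (median -0.61, 5 of 14 at least 2-fold lower, percentile 0.53), led by Lpl (-2.36 ± 0.20) and Abcg1 (-1.50 ± 0.21), with Pltp above 0 (0.76 ± 0.21). So were fatty acid oxidation and PPAR targets (-0.48, or -0.47 with bounds, 16 of 21 below 0, percentile 2.29), with Pdk4 at -2.23 ± 0.23 and Acot1 at 1.64 ± 0.20. The unfolded protein and integrated stress response list was low at -0.50 (19 of 25 below 0, percentile 0.19), with Chac1 at -1.87 ± 0.20 and Trib3 at -1.56 ± 0.20 but Ddit4 at 0.91 ± 0.20. Abcg1, Pdk4 and Elovl6 fell below 2-fold with normexp correction, to -0.67, -0.88 and 0.995.

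Of the remaining lists only the endothelial one was called, low at -1.03 (5 of 11 at least 2-fold lower, percentile 1.23). With one-sided genes at their bounds its median was -0.86, inside the random range that started at -0.89, and normexp correction turned it to 0.18, so its direction is not settled. Its members went both ways, with Flt1 at -2.00 ± 0.20 and Egfl7 at 1.64 ± 0.21. The medians of the uncalled lists were 0.23 for oxidative phosphorylation, 0.22 for the housekeeping reference, 0.19 for reprogramming barriers and early regulators, 0.16 for glycolysis, 0.14 for epithelial genes and -0.00 for keratinocyte genes. They were -0.12 for p53 targets, -0.43 for neural, -0.54 for skeletal muscle, -0.60 for adipocyte and -0.68 for extraembryonic genes. After normexp correction the skeletal muscle, adipocyte and extraembryonic medians were 0.01, 0.13 and 0.17, so their directions are not settled. The medians of the fatty acid, p53 and keratinocyte lists lay above 0 with spike-in scaling, at 0.18, 0.22 and 0.34. Several of these lists held large changes in opposite directions. The keratins Krt8 (2.76 ± 0.20) and Krt7 (-1.04 ± 0.20) went apart, as did the p53 targets Bax (2.08 ± 0.06) and Gadd45a (-1.71 ± 0.20), while Tfrc, a transferrin receptor often used as a reference gene, was higher by 2.23 ± 0.07.

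Among single genes measured on both arrays, Nup210, a nuclear pore protein, had the highest ratio, 58.3-fold (5.87 ± 0.27), followed by Wnt16 (18.2-fold), Ccdc116 (17.1-fold), Helt (12.9-fold), Galnt15 (11.1-fold), Cited1 (9.69-fold), Ccnb1ip1 (9.41-fold) and Rps6ka6 (9.31-fold). The lowest were Defa1 (23.2-fold lower), Csta1 (17.1-fold), Srgn and Rnase2a (12.6-fold each), Rarb, a retinoic acid receptor (12.5-fold), Ptprt (12.2-fold), Zbp1 (12.1-fold) and Sult1a1 (11.3-fold). Syt7, Aadac and Slc35f2 were at least 10.6-fold, 10.5-fold and 10.3-fold higher. Acvr1c, Olfr1414, Cstdc5 and Robo4 were at least 29.6-fold, 17.9-fold, 13.2-fold and 13.0-fold lower. Acvr1c rested on its brightest probe, since the mean of its probes gave a log2 ratio of -1.45. Normexp correction brought Nup210 to 4.05, Csta1 to -1.50 and Rarb to -1.14, and the bounds of Acvr1c, Olfr1414, Cstdc5 and Robo4 to -1.29, -1.24, -1.20 and -0.96, the last below 2-fold. Defa1, Csta1, Rnase2a, Olfr1414 and Cstdc5 belong to families with very similar copies, whose signals a probe may share. Where a called gene had several measured probes, all of them pointed the same way for 97.3% of 331 higher and 92.7% of 495 lower genes.

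**Figure D2:**
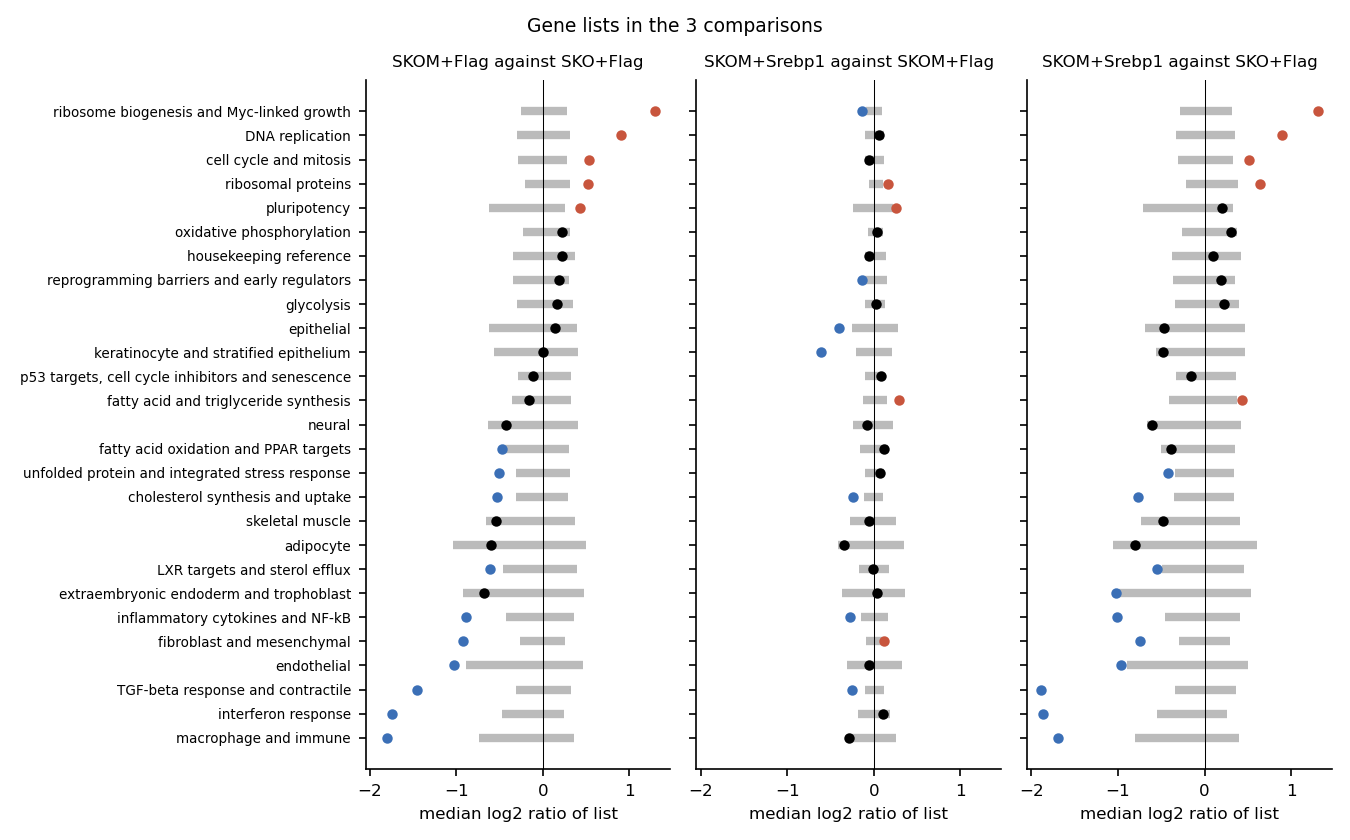
Median log2 ratio of each of the 27 gene lists (horizontal axis) in each comparison, with red points for lists called high, blue for low and black for uncalled, and grey bars spanning the central 95% of medians of 10000 matched random lists. Medians ran from -1.80 to 1.30 in SKOM+Flag against SKO+Flag but from -0.61 to 0.30 in SKOM+Srebp1 against SKOM+Flag, where all 4 lists called high turned negative with spike-in scaling and 3 of them with the median spike-in difference, constant shifts of all genes that leave the ranks among random lists as they are.

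SKOM+Srebp1 against SKOM+Flag shows what accompanied Srebp1 in the presence of c-Myc, and here group and slide cannot be told apart. The differences were smaller. Genes of fatty acid synthesis and desaturation were on balance higher relative to the bulk of genes, without a settled direction relative to the spike-in transcripts, while many enzymes of cholesterol synthesis, keratinocyte genes, and TGF-beta response and inflammatory genes were lower. Fads1, the delta-5 desaturase, was higher by 1.29 ± 0.20 and Scd1, the stearoyl-CoA desaturase, by 0.87 ± 0.20, whereas Msmo1 and Sqle, enzymes of sterol synthesis, had ratios of -1.12 ± 0.20 and -0.84 ± 0.20. Of 14846 genes measured, 250 were at least 2-fold higher (167 on both arrays and 83 by bound) and 351 at least 2-fold lower (231 and 120). The SD of ratios over genes was 0.40. Of the 51 genes picked for naming that had reached 2-fold, 26 fell below it after normexp correction. Lower calls made up 58.4% of calls, but 90.4% with spike-in scaling, which shifted the median of all genes by -0.37 from 0.00, and 70.0% after normexp correction. Ratios between 0 and 0.37 thus have no settled sign against the spike-ins, and what follows is relative to the bulk of genes.

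The fatty acid and triglyceride synthesis list had 16 of 21 members above 0 and a median of 0.30 (0.29 with bounds) at percentile 99.99. Relative to the spike-ins the median was near 0, at -0.07 with spike-in scaling and 0.027 when shifted by the median difference of the 8 spike-ins (-0.27). Besides Fads1 and Scd1, it included Lpin1 (0.84 ± 0.20), Fads2 (0.78 ± 0.20), Acss2 (0.71 ± 0.20), which makes acetyl-CoA from acetate, and Scd2 (0.69 ± 0.20). Fasn, the fatty acid synthase, stood at 0.35 ± 0.20, Thrsp was at least 1.21-fold higher, and Me1, malic enzyme, stood at -0.39 ± 0.20. The other members below 0 were Agpat2 (-0.23), Elovl5 (-0.17), Acaca (-0.10) and Elovl1 (-0.07), and the 4 probes of Acaca ranged from -0.38 to 0.34. Only Fads1 reached 2-fold among the members measured on both arrays. For the 10 members with a second probe the median was 0.06 with the brightest and -0.03 with the second probe, so the list's shift came mostly from members with 1 probe. Exceptions were Lpin1, whose 4 probes lay between 0.72 and 0.90, Acss2, whose 2 probes gave 0.71 and 0.66, and Fasn, whose 2 gave 0.35 and 0.33.

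The cholesterol list went the other way and was mixed, with 15 of 24 members below 0 and a median of -0.24 at percentile 0.04. Msmo1, Hsd17b7 (-0.87 ± 0.20), Idi1 (-0.86 ± 0.20), Sqle and Fdft1 (-0.81 ± 0.20) were lower, whereas Dhcr7 (0.65 ± 0.20) and Insig1 (0.52 ± 0.20) were higher. Over the 16 members with a second probe the median was -0.22 with the brightest and -0.25 with the second.

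**Figure D3:**
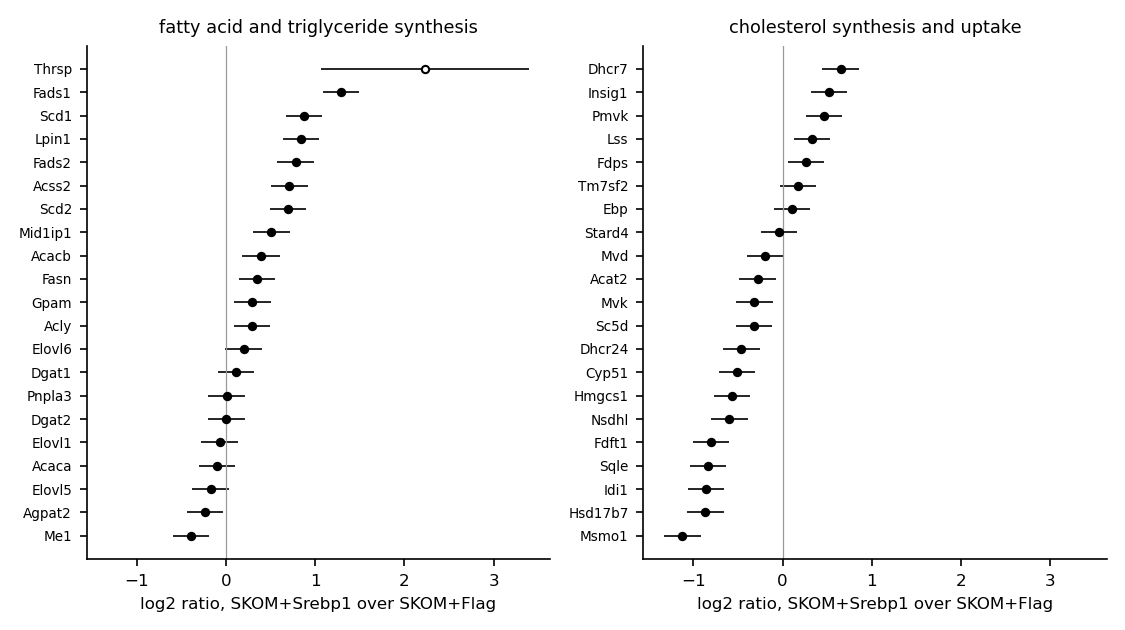
Log2 ratio of SKOM+Srebp1 over SKOM+Flag (horizontal axis) for measured genes of the fatty acid and cholesterol lists, not all cholesterol members being shown, with the scanner error as bars and an open point for the gene measured on 1 array only. Over all measured members the fatty acid list has a median of 0.30 and the cholesterol list of -0.24, or -0.07 and -0.61 with spike-in scaling and 0.027 and -0.51 with the median spike-in difference.

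Genes of stratified epithelium were lower with Srebp1. Of 15 keratinocyte genes, 13 lay below 0 and 5 were at least 2-fold lower, with a median of -0.61 at percentile 0, including Krt16 (-1.96 ± 0.20), Krt17 (-1.42 ± 0.20) and Lor (-1.11 ± 0.21), with Ly6d the other way (1.26 ± 0.21). The epithelial list was low as well (median -0.40, 10 of 13 below 0, percentile 0.22), with Krt7 at -1.27 ± 0.21 and Dsp, desmoplakin, at -0.88 ± 0.20, and its median was -0.07 without a filter on dim genes. Normexp correction left Ly6d at 0.61 and Krt7 at -0.94. Of 20 genes of TGF-beta response and contraction, 15 lay below 0 (median -0.25, percentile 0). The feedback inhibitors Smad7 (-1.88 ± 0.20) and Skil (-1.48 ± 0.20) were at least 2-fold lower, while Tgfbi stood at 0.56 ± 0.20. Normexp correction gave this list a median of -0.16. Inflammatory and NF-kB genes were low (median -0.28, 16 of 19 below 0, percentile 0.03), with the neutrophil attractant Cxcl5 at -1.59 ± 0.21 and Ptgs2 at -0.91 ± 0.06, and the median was -0.16 without a filter and -0.18 with the mean of each gene's probes.

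Other called lists moved by small amounts. The pluripotency list had a median of 0.26 (15 of 22 above 0, percentile 98.91), with Gdf3 (1.62 ± 0.33, but 0.037 after normexp correction) and Tfcp2l1 (0.85 ± 0.22) higher and Lin28b (-1.12 ± 0.29) and Klf5 (-1.04 ± 0.20) lower, the last 2 at -0.70 and -0.88 after normexp correction. Its direction is not settled, since the median was 0.13 without a filter, -0.07 after normexp correction, -0.11 with spike-in scaling and -0.0080 with the median spike-in difference. Fibroblast and mesenchymal genes had a median of 0.12 (21 of 32 above 0, percentile 98.7), which turned to -0.25 with spike-in scaling. Col3a1 (0.82 ± 0.20) and Postn (0.82 ± 0.20) were on the higher side, Twist1 stood at -0.52 ± 0.20, and Pdgfra went from 1.01 ± 0.09 to -0.06 after normexp correction. Ribosomal proteins (median 0.16, percentile 99.96) stood at 0.01 with quantile normalisation and -0.21 with spike-in scaling. Ribosome biogenesis genes were slightly lower (-0.14, 25 of 31 below 0, percentile 0.19, and -0.07 after normexp correction). Reprogramming barriers and early regulators had a median of -0.13 at percentile 2.25, with Dot1l, a histone methyltransferase, at -1.83 ± 0.21 (-0.95 for the mean of its probes). The 16 uncalled lists included cell cycle (-0.06), DNA replication (0.06), LXR targets (-0.01), glycolysis (0.02) and macrophage markers (-0.28, percentile 2.81). Of these, DNA replication and glycolysis turned to -0.31 and -0.35 with spike-in scaling. In the glycolysis list Slc16a3, a lactate exporter, was 4.56-fold higher.

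The highest single ratios were those of Zfp473 (7.08-fold), Clec2d (5.16-fold), Slc16a3, Zcchc13 (3.99-fold), Epha1 (3.76-fold), Mal2 (3.74-fold), Mgarp (3.66-fold) and Pex10 (3.64-fold). Zfp473 stood at 1.07 on the log2 scale when its probes were averaged. With normexp correction Zfp473, Zcchc13, Mal2, Mgarp and Pex10 fell below 2-fold, to 0.58, 0.21, 0.32, 0.59 and 0.95 on that scale, as did Rad9b, one of the lowest genes, to -0.98. The lowest were Rxfp3 (6.43-fold lower), Nab2 (5.53-fold), Lce1h (4.98-fold), Rad9b (4.94-fold), Prl3d2 (4.84-fold), Car2 (4.67-fold), Lce1g (4.60-fold) and Lce1i (4.55-fold). The Lce1 genes and the Prl3d genes belong to families of similar copies, so their values are uncertain as single genes, and Lce1g stood at -1.23 for the mean of its probes. Ano5, Tc2n, Klhdc7b and Ndp were at least 7.12-fold, 6.69-fold, 6.16-fold and 5.17-fold higher, but normexp correction left bounds of 0.52, 0.59, 0.40 and 0.26 log2 units, below 2-fold for all 4. Zswim2, Vmn1r236, Il13ra2 and S100a7a were at least 7.76-fold, 7.14-fold, 7.11-fold and 6.76-fold lower. All measured probes of a called gene pointed the same way for 77.8% of 45 higher and 89.7% of 39 lower genes with several.

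SKOM+Srebp1 against SKO+Flag sets c-Myc and Srebp1 together against neither, again across slides. Each gene's log2 ratio here is the sum of its ratios in SKOM+Flag against SKO+Flag and in SKOM+Srebp1 against SKOM+Flag. The values below are therefore not independent of those above. The picture was close to that of c-Myc with Flag, with growth and replication genes higher and contractile, interferon, macrophage and fibroblast genes lower. Nup210 was again highest (72.5-fold), and Prl3d2 and Prl3d1, placental prolactin family genes, were lowest (51.2-fold and 28.6-fold lower). Of 15051 genes measured, 1358 were at least 2-fold higher (1209 on both arrays) and 2184 at least 2-fold lower (1837 on both), and lower calls made up 61.7% of calls (64.2% with spike-in scaling).

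Ribosome biogenesis (median 1.31, 22 of 31 at least 2-fold higher), DNA replication (0.90, 12 of 25), ribosomal proteins (0.65, all 26 above 0) and cell cycle genes (0.51, 27 of 28 above 0) were at percentile 99.92 or above. With quantile normalisation the ribosomal protein median was 0.39. Fatty acid and triglyceride synthesis was called high here (0.43, 15 of 21 above 0, percentile 98.64), with Elovl6 (1.27 ± 0.20), Fads1 (0.96 ± 0.20) and Fasn (0.73 ± 0.20). With Thrsp at its bound the median was 0.37, just inside the random range that ended at 0.38. Cholesterol genes had a median of -0.77 (10 of 24 at least 2-fold lower, percentile 0), with Msmo1 at -2.37 ± 0.20, Hsd17b7 at -2.06 ± 0.20 and Nsdhl at -1.47 ± 0.20 (-0.83 for the mean of its probes). This is lower than in either other comparison because the list was low in both and the ratios add up.

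Of 20 TGF-beta response and contractile genes, 19 were at least 2-fold lower (median -1.89, percentile 0), with Smad7 at -2.81 ± 0.20 and Lmod1 at -2.31 ± 0.20. Interferon response (-1.87, 19 of 27 at least 2-fold lower), macrophage markers (-1.70, or -1.60 with bounds, 11 of 17), inflammatory genes (-1.01, 11 of 19) and fibroblast genes (-0.75, 12 of 32) were low, at percentile 0.01 or below. Examples were Usp18 (-2.59 ± 0.21), Tyrobp (-2.84 ± 0.22), Ptgs2 (-2.07 ± 0.06) and Dcn (-2.75 ± 0.20). LXR targets (-0.55) and the stress response list (-0.42) were low too. Endothelial (-0.97) and extraembryonic genes (-1.02) were called low, but with bounds their medians of -0.59 and -0.77 lay inside the random ranges. After normexp correction the medians of interferon, macrophage, endothelial and extraembryonic genes were -0.82, -0.59, -0.30 and -0.18. The pluripotency list was not called (0.20, percentile 93.3), yet 8 of 21 members were at least 2-fold higher, among them Fbxo15 (8.59-fold), Nr0b1 (at least 9.43-fold) and Gdf3 (at least 3.44-fold, or 0.71 log2 units after normexp correction). The other uncalled lists had medians between -0.80 (adipocyte) and 0.30 (oxidative phosphorylation).

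Other high ratios belonged to Galnt15 (24.9-fold), Ccdc116 (17.7-fold), Ccnb1ip1 (16.5-fold), Rcor2 (16.2-fold), Helt (14.1-fold), Mtfp1 (12.7-fold) and the cell cycle regulator E2f2 (12.6-fold), and other low ones to Rnase2a (18.7-fold lower), Lce1h (17.8-fold), Sema7a (17.6-fold), Lce1g (17.1-fold), Lce1i (16.7-fold) and Ucn3 (16.1-fold). Myb, Aadac and Tfap4 were at least 13.5-fold, 12.0-fold and 11.6-fold higher, and Dnmt3b was higher by at least 3.42 log2 units. Mab21l4, Defa1, S100a7a and Acvr1c were at least 48.5-fold, 44.7-fold, 37.4-fold and 31.6-fold lower.

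Genes called in SKOM+Flag were mostly called again in SKOM+Srebp1. Of the 1039 genes at least 2-fold higher in SKOM+Flag than in SKO+Flag, 803 (77.3%) were also at least 2-fold higher in SKOM+Srebp1 than in SKO+Flag and 2 at least 2-fold lower. Of the 1920 lower genes, 1563 (81.4%) were lower again and 1 was higher. These comparisons share the SKO+Flag array. Independent lists would share 88.4 and 283 genes, and simulations without any change shared 0.14 and 0.16 on average, with the scanner error as the only noise. These simulated overlaps are near 0 by construction, since that noise makes few 2-fold calls (3.55 on average). A departure of the SKO+Flag culture itself would enter both comparisons, and 1 array cannot measure it. Across 13849 genes, which are not independent replicates, the 2 ratios correlated at r = 0.896 against 0.502 in simulations without effects, with a covariance of 0.627 against 0.0241. When Srebp1 was added to c-Myc, 20 of the 1039 genes were a further 2-fold higher and 69 at least 2-fold lower. Of 1724 of the 1920 that could be measured there, 55 were at least 2-fold higher and 108 a further 2-fold lower. Over all genes measured in SKOM+Srebp1 against SKOM+Flag, 1.68% were at least 2-fold higher and 2.36% at least 2-fold lower. The 1039 and 1920 genes were picked by their SKOM+Flag values, which also enter the Srebp1 ratio. An error on that array would add reversed calls to both sets, and how many it added is not known. Across genes the Srebp1 ratio and the c-Myc ratio were nearly unrelated (r = 0.0371), whereas the shared SKOM+Flag array alone gave -0.498 in simulations, and the covariances were 0.0115 and -0.0239. The simulated correlations follow from the shared array by construction. They do not show how much agreement or opposition a departure of 1 culture would create.

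**Figure D4:**
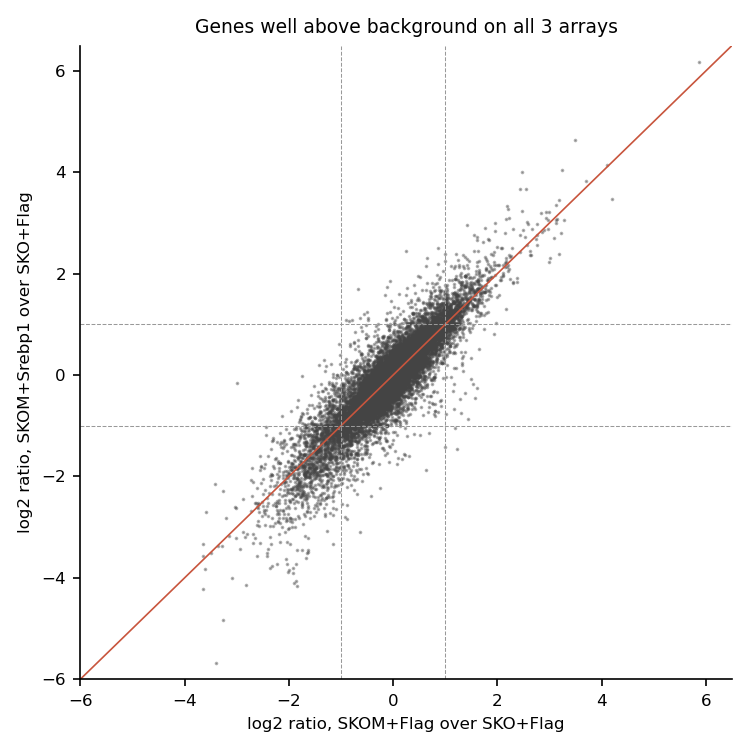
Log2 ratios of SKOM+Srebp1 over SKO+Flag (vertical axis) against those of SKOM+Flag over SKO+Flag (horizontal axis), with 1 point per gene well above background on all 3 arrays, a red line where both are equal and dashed lines at 2-fold. The 13849 genes lie along the line with r = 0.896. The shared SKO+Flag array alone gave 0.502 in simulations without effects, a value that follows by construction and does not measure a departure of that culture.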

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

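The tests of an array-wide shift, of both explanations for the spike-in shift and of slide effects were chosen after the results were seen, whereas those of a second macrophage gene set, an intensity trend and second probes were written down before theirs.

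Probes without a gene name, which no comparison in the report used, also differed between arrays. Of 10614 such probes, 518 of 3268 measured were at least 2-fold higher in SKOM+Flag than in SKO+Flag (240 lower), 130 of 3336 in SKOM+Srebp1 than in SKOM+Flag (249 lower) and 439 of 3267 in SKOM+Srebp1 than in SKO+Flag (313 lower). In SKOM+Flag against SKO+Flag, 15.9% of these probes were higher and 7.34% lower, against 6.93% and 12.8% of named genes. The shares in SKOM+Srebp1 against SKO+Flag were 13.4% and 9.58%, against 9.02% and 14.5%. The excess of lower calls among named genes thus did not hold for unnamed probes against SKO+Flag.

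Macrophage markers were lower in SKOM+Flag than in SKO+Flag (median -1.80), apart from Cd74, which was at least 2-fold higher. Their distance from the median of all genes, -1.74 (SD of random lists 0.27), is altered by no constant shift of all genes. It adds nothing to the list's percentile of 0, which had already set these markers apart from the bulk of genes. A shift of dim genes alone was not tested, and normexp correction brought the median to -0.49. A smaller share of macrophages in the SKOM+Flag culture may account for the lower markers. A second set of macrophage genes, none of them in another list (0), had a median of -1.40, with 18 of 21 below 0. It met the limit set beforehand, but narrowly, since the medians differed by -0.40 with a limit of 0.41. With one-sided genes at their bounds the medians were -1.57 for the first list and -0.79 for the second set, further apart than that limit. Not all members fell. Coro1a (0.053), Cyth4 (-0.11), Ptpn6 (-0.12), Pld4 (-0.24), Cd300a (-0.25) and Clec4n (-0.30) were nearly level, and Fcgr2b (0.92) and Ncf1 (at least 2.84-fold) were higher, and whether other cells express them was not tested. Lower expression within the same cells after c-Myc, which the design names, stays open and was not tested.

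All 8 spike-in transcripts, which are usually added in a fixed amount, were dimmer relative to the sample's own RNA on the SKOM+Flag array than on the SKO+Flag array, by a median of -0.30 (SD 0.0830). More messenger RNA per amount of total RNA in cells given c-Myc could dilute the spike-ins. The SKOM+Srebp1 culture should then show the same shift, yet its median against SKO+Flag was -0.014 (standard error over the 8 spike-ins 0.0375). That error holds no spread between arrays, since the 8 spike-ins shared the same arrays. The small median does not exclude the explanation, because the SKOM+Srebp1 array was alone on its slide. A difference between slides or an effect of Srebp1 could hide a shift. A spike-in amount or labelling step peculiar to the SKOM+Flag array is consistent with the 8 of 8 spike-ins that were dimmer there than on the SKOM+Srebp1 array too. The choice between these bears on the sign of several small list medians in SKOM+Srebp1 against SKOM+Flag.

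The fatty acid list lay above the cholesterol list in SKOM+Srebp1 against SKOM+Flag, by 0.53 between medians (SD of the difference for random lists 0.0898), a contrast within arrays that no scaling factor alters. An intensity trend is argued against, since the difference was 0.54 after a lowess curve on level was taken away. Odd probes cannot be told apart from a real difference: second-brightest probes gave 0.22, but they exist for only 10 fatty acid and 16 cholesterol genes, and among those 10 the brightest probes had a median of just 0.06. Another kind of slide difference cannot be told apart either, as 0 groups had arrays on both slides. An effect of the added Srebp1, the difference the design names, may account for the contrast and stays open.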

How the results depend on the processing

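Both scalings to the spike-in transcripts were chosen after seeing the data, and all other alternatives were set before. Of 68 recomputed counts 47 stayed within 1.5 times the main count. Of 126 recomputed medians of the 18 main list results, 121 moved by less than 1 SD of random lists, as did 398 of 441 for the other 63. Spike-in scaling entered the counts only and was left out of these medians and of the gene ratios below. It moved every list median by 0.34 in SKOM+Flag against SKO+Flag and by -0.37 in SKOM+Srebp1 against SKOM+Flag. Both shifts exceed 1 SD of random lists for every main list there. Of 2689 recomputed ratios of the 402 named gene results, 2446 moved by less than the scanner error, but with normexp correction this held for 200 of 391 only, and settings such as no filter leave a gene's ratio unchanged by construction. Of the named genes at 2-fold or more, 24, 26 and 16 fell below it with normexp correction and 83, 25 and 100 did not, in the order SKOM+Flag against SKO+Flag, SKOM+Srebp1 against SKOM+Flag and SKOM+Srebp1 against SKO+Flag. Normexp correction, whose offset by construction shrinks ratios of dim genes, gave 543 higher and 891 lower genes in SKOM+Flag against SKO+Flag, 42 and 98 in SKOM+Srebp1 against SKOM+Flag, and 787 and 1197 in SKOM+Srebp1 against SKO+Flag, with 422 higher and 729 lower genes shared between the first and the last. In SKOM+Srebp1 against SKOM+Flag it gave medians of -0.071 for ribosome biogenesis and 0.00342 for cell cycle genes, and reversed pluripotency to -0.071 and Pdgfra to -0.063. In SKOM+Flag against SKO+Flag it reversed the endothelial median to 0.18 and Sox7, at -1.26 in the main setting, to 0.24. Normexp correction also turned the medians of the uncalled skeletal muscle, adipocyte and extraembryonic lists there above 0, to 0.01, 0.13 and 0.17. The cause of these reversals was not tested. Keeping only genes well above background on both arrays left 231 lower genes with Srebp1 over SKOM+Flag, by construction the lower calls without bounds. No filter gave 539 and 626 there, and pluripotency medians of 0.11 with c-Myc and 0.13 with Srebp1. The 1.5-fold rule gave 2631 and 3602, 968 and 1079, and 3024 and 3933. Spike-in scaling gave 2248 and 1112 for SKOM+Flag against SKO+Flag and 101 and 946 for SKOM+Srebp1 against SKOM+Flag. Of 11 lists called in the latter, 4 changed sign with it and 3 with the median spike-in difference, which leaves the fatty acid median at 0.027, and of 15 in each other comparison 0 did with either. These are constant shifts of all genes, so the ranks behind the calls stay as they are. No paired analysis was possible because each group had 1 array.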

Other observations

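The 5 gene lists below were chosen after the genes that prompted them had been seen, but their members had not been looked at, and each list's test was written down before its result; the members named as examples were chosen after their values were seen.

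Genes that supply nucleotides were higher with c-Myc. Of 22 genes of purine, pyrimidine and one-carbon synthesis other than Cad and Shmt1, which prompted the list, 10 were at least 2-fold higher in SKOM+Flag than in SKO+Flag and 21 lay above 0 (median 0.94, percentile 100). Gart (1.78 ± 0.20), Mthfd1 (1.75 ± 0.20) and Impdh2 (1.57 ± 0.20) were among them, and the median was 0.81 in SKOM+Srebp1 against SKO+Flag. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for protein synthesis, were higher by less (median 0.35, 17 of 20 above 0, percentile 98.52), with Farsb at 1.23 ± 0.20 and Vars at 1.16 ± 0.20 but Wars and Aars at -0.68 each. Against SKO+Flag, SKOM+Srebp1 gave that list 0.22 at percentile 87.9.

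The immediate early list, which holds genes that serum and growth factors induce, was lower with Srebp1. Of 24 measured, 22 lay below 0 in SKOM+Srebp1 against SKOM+Flag and 5 were at least 2-fold lower (median -0.41, percentile 0). Among those 5 were Fosb (-1.86 ± 0.22), Egr3 (-1.82 ± 0.33), Phlda1 (-1.50 ± 0.20) and Fosl1 (-1.31 ± 0.20). Fos itself was higher (0.40 ± 0.07), and Nr4a2 (0.03), Egr2 (-0.04) and Dusp6 (-0.07) were nearly level. The same list was already lower in SKOM+Flag than in SKO+Flag (-0.72). In SKOM+Srebp1 against SKO+Flag, where both ratios add up, it stood at -1.23. Cornified envelope families had a median of -0.61 with Srebp1 (10 of 11 below 0, percentile 0.04). These are the Lce and Sprr genes of the outer skin, without those that prompted the list and without several Sprr genes already seen. These families too were already lower in SKOM+Flag than in SKO+Flag (-0.90, 13 of 13 below 0, percentile 1.685). Their median in SKOM+Srebp1 against SKO+Flag, where both ratios again add up, was -1.635. Members of each family resemble one another, so some probes may share transcripts. With Srebp1 the Lce members measured on both arrays ranged from -1.13 (Lce1f) to 0.38 (Lce1l). The Sprr2 members lay closer together, from -0.79 (Sprr2e) to -0.47 (Sprr2k). The time between feeding and harvest, or the slide, could give the same values as an effect of Srebp1, and nothing here decides between them. Klf4, an SKO factor, was also lower in SKOM+Srebp1 than in SKOM+Flag (-0.84 ± 0.20), and whether that bears on these lists was not tested.

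Genes induced by low oxygen formed a weaker group. After Slc16a3, Aldoc, Pdk1, Mgarp and Ddit4 had been seen to be higher with Srebp1, 24 other such genes had a median of 0.14 (15 above 0), at percentile 97.64 barely past the limit for a call, and -0.23 with spike-in scaling. Bnip3 (0.97 ± 0.20) and Ankrd37 (0.87 ± 0.20) were higher, whereas Bhlhe40 stood at -1.15 ± 0.20 and Adm at -0.54 ± 0.20. A low-oxygen response may be part of the difference, but these values do not settle it.

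Zfp473 was low on the SKOM+Flag array alone, at -5.21 log2 units against -2.22 in SKO+Flag and -2.39 in SKOM+Srebp1. Its level on SKOM+Flag was near the lowest signal well above background there (-5.46). As given above, normexp correction brought its ratio with Srebp1 below 2-fold.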
